A study of Arabidopsis thaliana with 12 samples.

How the data were processed

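Total RNA from aerial rosettes was labelled with biotin and hybridized to 12 Affymetrix ATH1 arrays, per the labels, with 3 arrays for each combination of time (night or subjective day) and treatment (1 h of white light or none). The labels give the night samples as CT 6 and the subjective-day samples as CT 18. Counted from subjective dawn, as is usual, CT 6 lies in the subjective day and CT 18 in the night, so the stated hours conflict with the titles unless they count from another point. Groups follow the sample titles, and whether those hours count from lights-off is not given in the sources used here. The deposited table gives one intensity per probe set and array on a linear scale. MAS5 is the only tool that the labels name, and its version, settings and target level are not given in the sources used here. The values showed that the table had not been scaled to a common level, with 2% trimmed means from 65.9 to 176.5 per array. Detection calls and raw image files were not used here.

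The table held 22810 probe sets, of which 64 control probe sets were left out of the tests. Of the other 22746, the annotation table used here named 1 gene for 13513, several for 503, and did not list 8730. Only genes of probe sets with 1 name are named, and 13436 of these matched the TAIR10.1 gene set by identifier. Many well-known genes fall among the probe sets without a name, so of 326 genes in the lists fixed in advance 48 had a named probe set and 39 were tested. No genome positions are given because the build behind the array annotation is not given in the sources used here. One probe set per gene, that with the highest mean, stood for a gene in the lists, and none of the 52 genes with 2 or more tested probe sets was called in opposite directions by a pulse.

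Signals were raised by 2 (the 10th percentile of all values, rounded), taken to log2 and then quantile normalized across the 12 arrays. Normalized signals are these values taken back to a linear scale, less 2. The plan made before the data were examined assumed scaled arrays and no further normalization. It was changed to quantile normalization, which had been planned as an alternative, when the trimmed means were seen and before any comparison between groups, and the fit without normalization is given as an alternative. Probe sets with a mean log2 value above the 40th percentile were kept, 13647 in all, of which 7331 name 1 gene, and the lowest mean signal kept was 21.75. The 4 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, 8 residual degrees of freedom, median total 13.26). A probe set was called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were pulse minus control at night, the same in the subjective day, the difference of these (night minus day), and night minus day controls. All limma, camera and fry tests were two-sided. The p-values measure the spread between arrays, which the labels do not say came from separate plants or cultures.

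Genes were named by a rule set before the data were examined. For each pulse it took the 8 largest rises and falls among called probe sets with 1 gene whose pulsed and control arrays did not overlap, 14 clock and light genes whatever their result (of which GI alone had a named probe set), and up to 4 members with the smallest p of each list described. For the difference between pulses and for the controls it took the 6 largest in each direction. The lists of clock, light signalling, flavonoid, chlorophyll, Calvin cycle and starvation genes were fixed before the data were examined. Those of cold, autophagy, amino acid breakdown, nuclear photosynthesis, plastid-encoded, GSTU, SWEET, tubulin and cell wall genes were drawn up after the annotation was seen and before any comparison between groups, and which lists to describe was decided after the results were seen. Lists with at least 3 tested members, 19 in all, were tested with camera at its preset correlation of 0.01, again with an estimated correlation, and with fry. Camera called 3, 5, 4 and 5 lists for the 4 contrasts in that order, and none with an estimated correlation, where fry called 4, 12, 9 and 12. Fry tests whether a list's genes move one way and does not compare them with other genes.

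Where a group mean lay under 21.75 the fold was computed with both means set to at least that signal and is given as "at least", a method chosen after seeing the data. Where dim groups could move a difference between pulses either way, the difference is given as not measured. The ranking of genes by size used the fitted changes, also for such genes. Whether the replicate numbers pair the arrays of different groups stays open. Same-numbered arrays had correlations of their deviations from -0.1082 to 0.4462, and 8 of 18 pairs passed 0.1. Among night pulse, night control and day pulse arrays these were 0.1161 to 0.4462 for replicates 1 and 2. For replicate 3 they were -0.04905 to -0.02365, and pairs with a day control had -0.1082 to 0.1471. No block was fitted in the main model. A replicate block raised the calls from 1760 to 1964 for the night pulse and from 5833 to 6214 for the day pulse. For the difference they rose from 1728 to 2019, and for the controls from 6602 to 6928. No 2 of the 66 pairs of arrays were identical.

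The alternatives were other pseudocounts, other filters, no normalization, median centring, limma without a trend, robust or with array weights, a replicate block, only the compared groups, stricter thresholds and each array left out in turn. Leaving out both arrays with a high GAPDH ratio, and testing lists with median centring or without night pulse replicate 3, were added after seeing the data, as was a fit with every normalized signal raised to at least 21.75, in which the spread of dim signals is reduced by construction, and the alternatives run for every tested member of a list and every contrast of a named gene. The tests were checked on simulated data with 3 arrays per group. These had independent normal noise, the same spread of a gene in every group and far fewer changed genes than were called here. The shares that follow need not hold for the real data. Of 100 genes changed by 1 log2 unit, 40% were recovered for the night pulse, 45% for the day pulse, 9% for the difference and 43% for the controls. At 2 log2 units these shares were 80%, 88%, 56% and 86%, and 5.00% to 8.45% of calls were false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.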

Results

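Gene expression was measured on 12 Affymetrix ATH1 arrays with total RNA from aerial rosettes of wild-type Arabidopsis thaliana seedlings of the Columbia ecotype. The seedlings were 15 days old and had been raised under 12 h of white light and 12 h of darkness before a transfer to constant darkness. They received a 1 h pulse of white light at night or in the subjective day, or were collected at the same times without a pulse. This gave 4 groups of 3 arrays, called night pulse, night control, day pulse and day control. Before normalization the median signal per array ran from 23.5 to 63.5 and the 2% trimmed mean from 65.9 to 176.5, and the number of arrays limits the precision. The ratio of 3' to 5' GAPDH control signal, a sign of RNA quality, was 9.29 on day pulse replicate 1 and 8.75 on day control replicate 2, against 2.16 to 5.16 on the other arrays. The same ratio for actin was 37.1 on night pulse replicate 3, against 13.5 to 27.7 on the other arrays. The first principal component held 51.25% of the variance and set the 3 day controls, at 91.48 to 108.2, apart from the other groups. Signals are given normalized, as mean ± SD over 3 arrays, log2 changes are limma estimates ± SE with n = 3 arrays per group, and "at least" marks folds against a mean signal under 21.75.

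The first comparison asked which genes responded to light given at night. GI (AT1G22770), a clock gene whose transcript normally peaks late in the day, rose from 9.12 ± 9.04 in the night controls to 171 ± 45.9 after the pulse, at least 7.87-fold. HYH (AT3G17609), a transcription factor of light signalling related to HY5, rose by 1.76 ± 0.21 log2, from 112 ± 12.9 to 383 ± 33.3. UGT78D2 (AT5G17050) and UGT78D1 (AT1G30530), which attach sugars to flavonoids, rose by 2.43 ± 0.37 and 2.05 ± 0.23. AT3G15450, one of the dark- and sugar-starvation genes listed in advance, fell from 2577 ± 326 to 141 ± 51.7. ATG8E (AT2G45170), a gene of the ATG8 family that builds autophagosomes, fell from 482 ± 33.5 to 50.8 ± 13.6.

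Among genes chosen by the size of their fitted change, AT2G27420, a cysteine protease family gene, rose from 6.15 ± 7.87 to 309 ± 22.3, at least 14.2-fold. AT3G14200 and AT2G20560, which encode DnaJ-type chaperones, rose at least 11.3-fold and 5.51-fold. AT1G20070 rose 20.8-fold from 30.7 ± 14.6 to 654 ± 217. TBL26 (AT4G01080), of a family that acetylates cell wall polysaccharides, rose 15.4-fold, AT3G44450, an inhibitor of cryptochrome, 13.6-fold, and AT1G67360, a lipid droplet protein, 12.2-fold. AT2G20670 fell from 375 ± 21.0 to 17.5 ± 9.88, and AT5G61590, an ERF-type factor that represses wax synthesis, fell from 872 ± 137 to 45.7 ± 5.86. The glutaredoxin gene AT3G62950 fell from 130 ± 16.7 to 9.21 ± 9.72, at least 5.96-fold. AT5G19120, of the aspartyl protease family, fell by 3.96 ± 0.27 log2, AT1G23390, an F-box protein that acts on chalcone synthase, by 3.68 ± 0.37, and AT3G15630 by 3.43 ± 0.30.

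Of the dark- and sugar-starvation genes, 2 of 4 tested fell, AT3G15450 and ATG8E, and 3 fell when adjusted over the list alone. IVD, an enzyme of leucine breakdown, changed by -0.41 ± 0.17 and ETFQO, which passes electrons from amino acid breakdown to respiration, by -0.28 ± 0.20, and neither passed the test over all probe sets, although IVD did without night pulse replicate 3 (adjusted p = 0.0491). The list had a camera adjusted p = 0.00086, and adjusted p = 0.22 with an estimated correlation. Of 10 autophagy genes (9 ATG8 genes and ATG3), 3 fell, 7 were not called and none rose, with ATG8F (AT4G16520) down by -1.34 ± 0.19 and ATG8C (AT1G62040) by -0.60 ± 0.16. Camera gave this list an adjusted p = 0.053, or adjusted p = 0.89 with an estimated correlation, but 0.00689 without night pulse replicate 3 and 0.0419 without normalization, and under each other scaling 2 of its genes fell. The ATG8C call was lost without night pulse replicate 1 (adjusted p = 0.0906) or 2 (0.068), without night control replicate 2 (0.107) or 3 (0.0831), and under both other scalings (0.544 and 0.0686).

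Of 15 cold and dehydration genes, 3 rose, 2 fell and 10 were not called (adjusted p = 0.68, and adjusted p = 0.89 with an estimated correlation). COR15A (AT2G42540) and COR15B (AT2G42530), which encode chloroplast proteins that protect against freezing, rose by 2.60 ± 0.36 and 2.79 ± 0.48. COR27 (AT5G42900), a light- and cold-regulated repressor, fell by 2.64 ± 0.31. XERICO (AT2G04240), a RING protein of abscisic acid metabolism, fell by 0.78 ± 0.20, a call lost without night pulse replicate 1 (adjusted p = 0.0814) or 3 (0.0931), without night control replicate 2 (0.0918) or 3 (0.059), and without normalization (0.393).

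The 1 tested gene of the evening clock list (GI), the 1 of the light signalling list (HYH) and both of the flavonoid list rose, also when adjusted over the list alone. Of 4 chlorophyll synthesis genes, 2 fell, also when adjusted over the list alone, and 2 were not called (adjusted p = 0.206, and adjusted p = 0.613 with an estimated correlation). PORB, a light-dependent protochlorophyllide reductase, fell by 0.78 ± 0.17 and the methyltransferase CHLM by 0.55 ± 0.13. Both lost the call without normalization (adjusted p = 0.278 and 0.714) and with median centring (0.107 and 0.272), and CHLM also without night pulse replicate 3 (0.0621) or night control replicate 2 (0.061) or 3 (0.05). Of 4 GSTU glutathione transferase genes, 1 rose (0 without normalization and 2 with median centring), GSTU16 (AT1G59700) by 0.92 ± 0.18, a call lost without normalization (adjusted p = 0.153), while GSTU20 (AT1G78370) had a value of 1.09 ± 0.37 (adjusted p = 0.0781). GSTU20 was called under 9 of its alternatives, over which its adjusted p ran from 0.00599 to 0.277, among them those without day control replicate 1 (0.026) or 2 (0.0196). This list had an adjusted p = 0.0372, or adjusted p = 0.22 with an estimated correlation, 0.0518 without night pulse replicate 3 and 0.0692 without normalization. None of 26 plastid-encoded photosystem and cytochrome b6f genes was called by limma and 1 had an unadjusted p under 0.05, with a median change of -0.70 (adjusted p = 0.0368, and adjusted p = 0.89 with an estimated correlation). Night pulse replicate 3 was low in plastid-encoded genes, with a mean log2 of 8.37 against 10.4 and 10.28, and without it the list had an adjusted p = 0.807, while with median centring it had 0.0583.

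In all, limma called 1760 of 13647 probe sets after the night pulse, 829 higher and 931 lower, of which 1119 changed at least 2-fold. Higher probe sets made up 47.1% of the calls, and 63.8% of the 669 made without normalization. The pulsed and control arrays did not overlap for 37.11% of all probe sets, where chance gives 10%. Without night control replicate 2 the count was 1105.

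**Figure D1:**
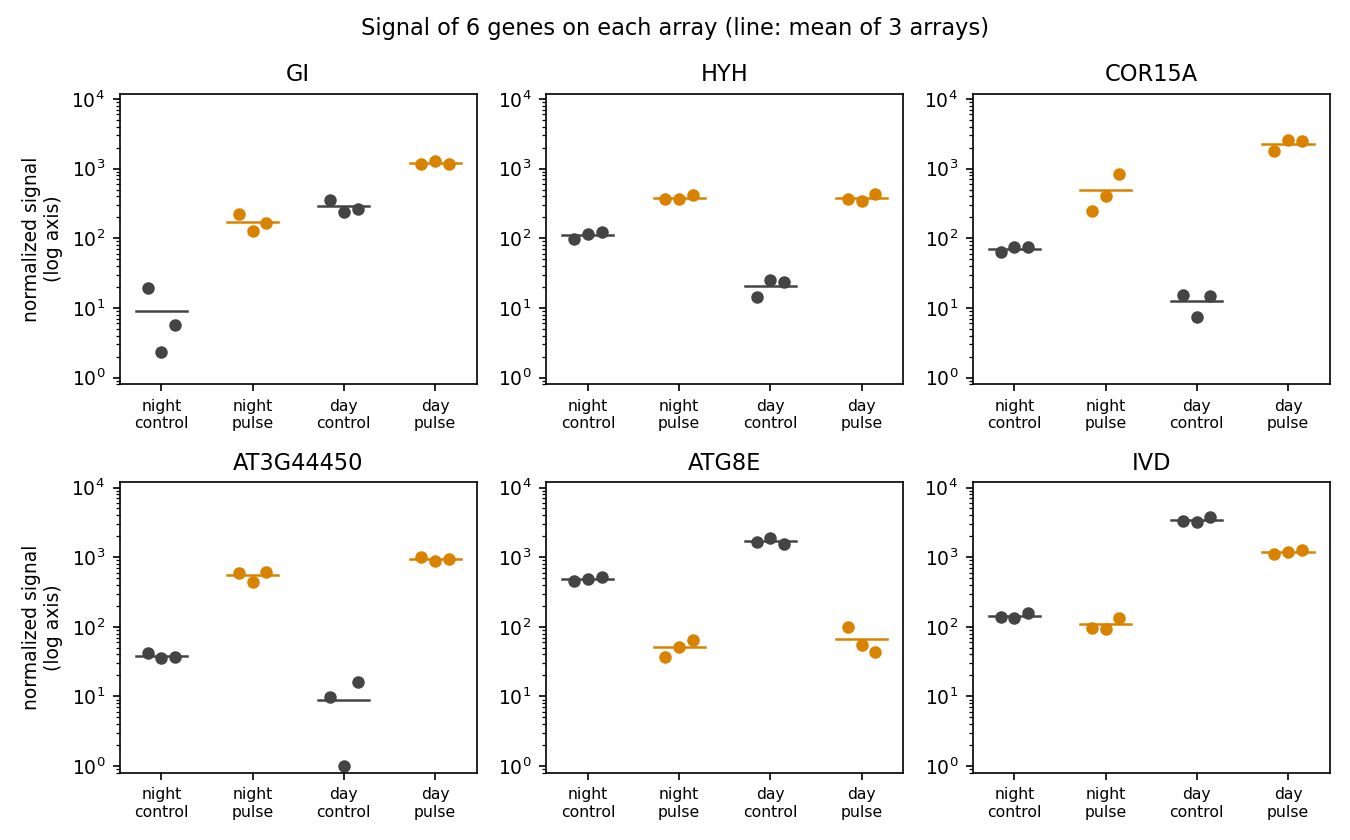
Normalized signal of 6 genes on each of the 12 arrays, with a log axis, points for arrays, orange for pulsed and grey for control groups, and lines for group means of 3 arrays. GI, HYH, COR15A and AT3G44450 lay higher on every pulsed array than on any control array of the same time, ATG8E lay lower on every pulsed array, and IVD was far higher in the subjective day, with means of 3412 and 1189, than at night. Values under 1, which applies to AT3G44450 on day control replicate 2 at 0.549, are drawn at 1.

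The second comparison asked which genes responded to the same pulse in the subjective day. COR15A rose from 12.4 ± 4.46 to 2281 ± 425, at least 105-fold, and COR15B from 15.9 ± 9.85 to 1274 ± 204, at least 58.6-fold. HYH rose from 20.8 ± 5.71 to 379 ± 47.6, and GI from 286 ± 63.6 to 1210 ± 81.6, a change of 2.09 ± 0.43 log2. ATG8E fell from 1688 ± 186 to 65.9 ± 28.7, and all 10 autophagy genes tested fell. MCCB (AT4G34030), an enzyme of leucine breakdown, fell from 4112 ± 434 to 1290 ± 362.

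Of the genes chosen by size, AT1G51090, a protein with a heavy-metal-associated domain, rose from 4.25 ± 2.32 to 1095 ± 192, at least 50.3-fold. AT3G44450 rose at least 43.6-fold, AT1G06000, a flavonol rhamnosyltransferase, at least 15.3-fold, AT1G20030, of the thaumatin family, at least 13.1-fold, and AT1G13650 at least 11.7-fold. AT1G20070 rose 68.3-fold from 24.4 ± 15.1 to 1632 ± 69.5. AT3G62950 fell from 1229 ± 145 to 0.585 ± 0.0555, at least 56.5-fold. AT2G20670 fell 90.4-fold, AT5G19120 32.5-fold, AT1G54740 31.6-fold, AT3G07350 31.1-fold and AT5G61590 31.0-fold. AT1G50040 and AT4G16000 fell at least 11.1-fold and 9.74-fold.

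All 4 dark- and sugar-starvation genes tested fell, also when adjusted over the list alone (adjusted p = 0.0018, and adjusted p = 0.20 with an estimated correlation). AT3G15450 fell by 3.81 ± 0.25, IVD by 1.52 ± 0.17 and ETFQO by 0.93 ± 0.20. The fall of all 10 autophagy genes, 9 without normalization, had an adjusted p = 4.9e-05, and adjusted p = 0.34 with an estimated correlation. ATG8F fell by 2.47 ± 0.19, APG8A (AT4G21980) by 1.49 ± 0.18 and ATG8C by 1.38 ± 0.16. Of 15 genes listed for branched-chain amino acid breakdown and electron transfer, 9 fell, 1 rose and 5 were not called (adjusted p = 0.0189, and adjusted p = 0.34 with an estimated correlation), against 6 falls without normalization and 13 with median centring. The list also held related genes that encode neither branched-chain breakdown enzymes nor electron transfer flavoproteins, NDB2 and PPDK among them. MCCB fell by 1.70 ± 0.19 and ETFBETA (AT5G43430) from 530 ± 177 to 179 ± 9.37, while NDB2 (AT4G05020), an alternative NADH dehydrogenase of mitochondria, rose by 2.31 ± 0.26.

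Of the cold and dehydration genes, 7 rose, 4 fell and 4 were not called. TIL (AT5G58070), a lipocalin, rose from 689 ± 148 to 1724 ± 547 and COR27 fell from 84.6 ± 13.7 to 13.1 ± 5.88, at least 3.89-fold. This list had a median change of -0.08, a mean of 0.98 and an adjusted p = 0.47 for a rise, and adjusted p = 0.75 with an estimated correlation. All 4 GSTU genes tested rose, GSTU18 (AT1G10360) by 1.84 ± 0.21 and GSTU27 (AT3G43800) by 1.19 ± 0.21 (adjusted p = 0.0212, and adjusted p = 0.20 with an estimated correlation). Under each other scaling 3 of the 4 rose, since GSTU16, at 0.66 ± 0.18, lost its call (adjusted p = 0.251 and 0.305), and without normalization the list had an adjusted p = 0.0685. Of 7 SWEET sugar transporter genes, 4 rose and 3 were not called (adjusted p = 0.0948, and adjusted p = 0.34 with an estimated correlation). SWEET17 (AT4G15920) rose by 2.98 ± 0.24, SWEET1 (AT1G21460) by 1.11 ± 0.19 and SWEET13 (AT5G50800) at least 4.7-fold. SWEET4 rose at least 1.66-fold, from a day control mean of 13.9, and lost its call without day pulse replicate 2 (adjusted p = 0.0678) or 3 (0.0933) or day control replicate 3 (0.0586), and with dim signals raised to 21.75 (0.152).

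UGT78D2 and UGT78D1 rose by 3.56 ± 0.37 and 2.41 ± 0.23, so both tested genes of the flavonoid list rose, as did GI and HYH for theirs, also when adjusted over the list alone. Of 31 nuclear photosynthesis and Calvin cycle genes, 11 rose, 3 fell and 17 were not called, but with median centring 4 rose and 7 fell, without normalization 7 rose and 1 fell, and the median change went from 0.23 to -0.09. CaS (AT5G23060), a thylakoid calcium sensor, rose by 2.29 ± 0.19, NdhN (AT5G58260), of the chloroplast NDH complex, by 1.13 ± 0.19, and SBPASE (AT3G55800), of the Calvin cycle, by 0.94 ± 0.15, a call lost with median centring (adjusted p = 0.0742). The list as a whole had an adjusted p = 0.134, and adjusted p = 0.53 with an estimated correlation. Of 4 chlorophyll synthesis genes, 2 fell, also when adjusted over the list alone, PORB by 0.81 ± 0.17 and CHLM by 0.39 ± 0.13 (adjusted p = 0.274, and adjusted p = 0.52 with an estimated correlation). CHLM lost its call under 9 of 25 alternatives. These were leaving out day pulse replicate 1 (adjusted p = 0.0579), 2 (0.0581) or 3 (0.052), day control replicate 2 (0.0842) or both arrays with a high GAPDH ratio (0.125), and no normalization (0.117), no filter (0.068), limma without a trend (0.0608) and only the compared groups (0.135). CHLI2 changed by -0.36 ± 0.18 and HEMA2 by -0.22 ± 0.33 without a call, although array weights called both (0.0114 and 0.0132) and median centring called CHLI2 (0.0407). Without day pulse replicate 3 HEMA2 changed by 0.03. Of 20 plastid-encoded transcription and translation genes, 9 rose and 11 were not called (adjusted p = 0.029, and adjusted p = 0.62 with an estimated correlation), but 3 rose without normalization (adjusted p = 0.0892) and 0 with median centring. Day control replicates 2 and 3 were lower in plastid-encoded genes, at mean log2 values of 9.12 and 9.23, than replicate 1 at 10.39.

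After the subjective-day pulse limma called 5833 of 13647 probe sets, 2864 higher and 2969 lower, of which 3698 changed at least 2-fold. Higher probe sets made up 49.1% of the calls, but 33.9% with arrays centred on their medians, a scaling that moved the median of all changes to -0.252. The arrays of both groups did not overlap for 48.0% of probe sets, where chance gives 10%. Without normalization 3721 were called, and without both arrays with a high GAPDH ratio, an alternative chosen after seeing the data, 5396 (2551 for the night pulse).

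**Figure D2:**
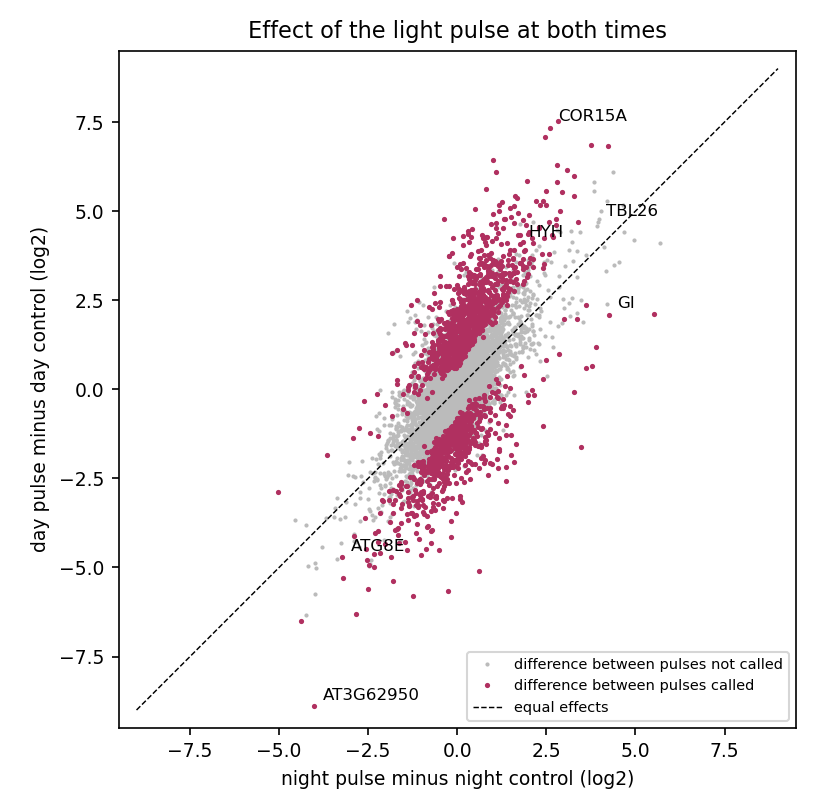
Change after the night pulse (horizontal, log2) and after the subjective-day pulse (vertical, log2) for each of 13647 probe sets, with red for the 1728 whose difference between pulses was called, grey for the others and a dashed line for equal effects. COR15A, HYH and ATG8E changed more in the subjective day. For AT3G62950, whose pulsed means were both under 21.75, the difference was not measured. GI had the larger fitted change at night, but its difference was not called with signals raised to at least 21.75.

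The third comparison asked whether a pulse acted alike at both times, and tested the difference between its effects. Because many of these genes had a group mean under 21.75, their differences were also fitted with all signals raised to at least 21.75, an alternative chosen after seeing the data. Raised signals also reduce the spread of dim groups. COR15A rose more in the subjective day than at night, with a difference (night minus day, log2) of -4.74 ± 0.52 as fitted and -3.96 ± 0.46 with raised signals. The same differences were -3.52 ± 0.67 and -2.86 ± 0.54 for COR15B, and -2.33 ± 0.29 and -2.15 ± 0.25 for HYH. HYH reached 383 after the night pulse and 379 after the day pulse, from control means of 112 and 20.8. For the glutaredoxin gene AT3G62950 both pulsed means were under 21.75, so the sizes of its falls, and the difference between them, were not measured. For GI the fitted difference was 2.15 ± 0.60 (adjusted p = 0.033), but its night control mean was 9.12, and with raised signals the difference was 0.74 ± 0.30 without a call (adjusted p = 0.117). The GI call was also lost without any 1 of 9 of the 12 arrays, with adjusted p from 0.0505 without day control replicate 2 to 0.0791 without night control replicate 3, and without normalization (0.0787). Its difference was then 1.62 to 2.29 with 1 array left out and 2.41 without normalization.

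Of the genes chosen by size, AT1G13650, AT5G21100, of the ascorbate oxidase family, and AT1G70820 had fitted differences of -5.44 ± 0.48, -4.01 ± 0.73 and -3.99 ± 0.39, against -2.47 ± 0.39, -2.57 ± 0.49 and -3.36 ± 0.27 with raised signals, since their day control means were under 21.75. For AT1G20030 and AT1G51090 both control means were under 21.75, so the difference between their rises was not measured. AT2G38820, AT3G02340, ATL8 (AT1G76410), a RING ubiquitin ligase, and AT2G32150, of a hydrolase family, fell after the day pulse, with changes of -4.51, -4.66, -4.47 and -4.31, and had values of -0.52, -1.02, -0.87 and -0.75 without a call at night. At night they were called under 1, 5, 3 and 5 alternatives, for AT3G02340 with raised signals among them (adjusted p = 0.0403). With raised signals the night minus day difference of their controls was -3.93, -2.83, -4.55 and -5.29. A lower start at night and a weaker action of light cannot be told apart here. Differences between pulses for these genes were 4.0 ± 0.29, 3.64 ± 0.72, 3.60 ± 0.52 and 3.56 ± 0.34, and with raised signals that of AT3G02340 was 3.19 ± 0.44. The night pulse mean of ATL8 was 20.9, so a larger fall at night was not excluded. AT1G69570, a Dof-type factor, had a fitted difference of 3.63 ± 0.84, and 2.17 ± 0.38 with raised signals, since its night control mean was 11.4.

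Of the 10 autophagy genes, 6 differed between the pulses, all with positive values, among them APG8A at 1.52 ± 0.26, ATG8B (AT4G04620) at 1.80 ± 0.36 and ATG8H (AT3G06420) at 2.28 ± 0.49 (adjusted p = 5.9e-05, and adjusted p = 0.47 with an estimated correlation), against 5 without normalization and 8 with median centring. All 6 fell in the subjective day. At night ATG8E, ATG8F and ATG8C fell as well, ATG8H was not called, and APG8A and ATG8B changed by 0.03 and 0.32 without a call. All 10 genes were lower in the night controls, so a lower start and a weaker action of light cannot be told apart here either. Of the 15 genes of the branched-chain breakdown and electron transfer list, 4 had called differences, also positive, MCCB by 1.46 ± 0.27, ETFBETA by 1.54 ± 0.33, IVD by 1.11 ± 0.24 and PPDK, a pyruvate phosphate dikinase (AT4G15530) of neither group, by 1.11 ± 0.27 (adjusted p = 0.0076, and adjusted p = 0.47 with an estimated correlation). At night ETFBETA and PPDK changed by 0.04 and 0.29 without a call. These 4 genes were also lower in the night controls, so the same limit holds for them. ETFBETA, IVD and PPDK lost the call without normalization (differences of 1.66, 1.37 and 1.47, adjusted p = 0.0881, 0.109 and 0.0602), where 1 of the 15 was called, against 8 with median centring. The plastid-encoded photosystem list (4 of 26 called, all negative, adjusted p = 0.00018) and the transcription and translation list (1 of 20, negative, adjusted p = 0.00042) differed too, each with adjusted p = 0.47 with an estimated correlation. Without night pulse replicate 3, low in these genes, the adjusted p was 0.014 and 0.0113, and neither other scaling left any member called.

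Many probe sets were called in the same direction at both times. Of 829 called higher at night, 697 were also called higher in the subjective day (84.1%, 174 expected for independent calls, odds ratio 25.94). Of 931 called lower, 740 were also called lower (79.5%, 202.5 expected, odds ratio 18.23). One-sided Fisher's exact tests gave log10 p of -359.1 and -337.3. Both lists came from 1 fit with a shared estimate of the spread per probe set, so the calls were not independent. The expected counts and these p-values are therefore no exact measure of chance. UGT78D1 and AT5G61590 were among those called the same way at both times without a called difference. A missing call does not show equal effects. Of the 1437 shared calls, 1070 had the larger change in the subjective day, and 38 probe sets were called in opposite directions. Among the shared calls a difference was called for 366 with the larger change in the subjective day and 19 with the larger change at night. The median ratio of day to night size was 1.42. Changes at both times had r = 0.661 and rho = 0.570 across probe sets, which are not independent replicates. Limma called a difference for 1728 probe sets, 709 positive and 1019 negative, with the larger change in the subjective day for 1601 of them, as fitted and with dim groups included. The positive share was 41.03%, and 74.7% of 2728 with median centring (median of all, 0.306). Without normalization 439 were called, without night control replicate 3 1147, and without day control replicate 1 2650.

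The fourth comparison set the night controls against the day controls, named by their titles, with no pulse in either. IVD (AT3G45300), MCCB and ETFQO (AT2G43400), of amino acid breakdown, were lower at night. IVD had 143 ± 12.6 against 3412 ± 285, MCCB 249 ± 8.29 against 4112 ± 434 and ETFQO 79.7 ± 7.55 against 1440 ± 297. AT4G33150, an enzyme of lysine breakdown, had 68.5 ± 10.8 against 3779 ± 746. GI was at least 13.2-fold lower at night. CaS and NdhN were higher at night, by 2.94 ± 0.19 and 2.99 ± 0.19 log2.

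Of the genes chosen by size, GSTU20 was at least 22.0-fold higher in the night controls, at 479 ± 122 against 16.0 ± 10.6. The serine carboxypeptidase-like genes scpl35 (AT5G08260) and scpl46 (AT2G33530) were 16.0-fold and at least 5.93-fold higher. AT1G06000, AT5G62140 and AT3G03770, a receptor-like kinase, were higher at least 4.99-fold, 5.39-fold and 3.38-fold. AT1G19530 had 16.9 ± 6.35 against 2779 ± 890, at least 128-fold lower at night. AT5G39520, AT4G37220, of a cold acclimation protein family, AT3G19390, a granulin-type cysteine protease, and AT4G39675 were at least 63.7-fold, 58.1-fold, 29.1-fold and 12.1-fold lower.

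Of the 15 genes of the branched-chain breakdown and electron transfer list, 11 were lower at night (10 without normalization, where 1 was higher, and 12 with median centring) and 4 were not called (adjusted p = 2.5e-06, and adjusted p = 0.17 with an estimated correlation), with ALDH6B2 (AT2G14170), of valine breakdown, at -3.29 ± 0.16. All 10 autophagy genes were lower at night, 7 without normalization (adjusted p = 1.1e-05, and adjusted p = 0.35 with an estimated correlation), with ATG8B at -3.97 ± 0.26, APG8A at -2.43 ± 0.18 and APG8H (AT3G15580) at -1.38 ± 0.18. All 4 dark- and sugar-starvation genes were lower at night, also when adjusted over the list alone (adjusted p = 0.00078, and adjusted p = 0.18 with an estimated correlation). IVD, ETFQO and ATG8E belong to this list as well as to those before. Both flavonoid genes were higher at night, also when adjusted over the list alone, UGT78D1 by 1.29 ± 0.23 and UGT78D2 by 1.34 ± 0.37. Of 31 nuclear photosynthesis genes, 17 were higher, 4 lower and 10 not called (adjusted p = 0.0212, and adjusted p = 0.35 with an estimated correlation). With median centring 11 were higher and 12 lower (adjusted p = 0.199), and without normalization the adjusted p was 0.24. NdhL (AT1G70760) and SBPASE were higher by 1.62 ± 0.16 and 1.53 ± 0.15. Of 20 plastid-encoded transcription and translation genes, 12 were higher at night and 8 were not called (adjusted p = 0.0167, adjusted p = 0.55 with an estimated correlation, and 0.24 without normalization), while 4 were higher with median centring.

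Between the controls limma called 6602 of 13647 probe sets, 3511 higher at night and 3091 lower, of which 4169 differed at least 2-fold. The higher share was 53.2%, but 81.1% without normalization, where the median of all differences was 0.545, and 39.2% with median centring, where it was -0.186. The arrays did not overlap for 60.45% of probe sets, where chance gives 10%.

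**Figure D3:**
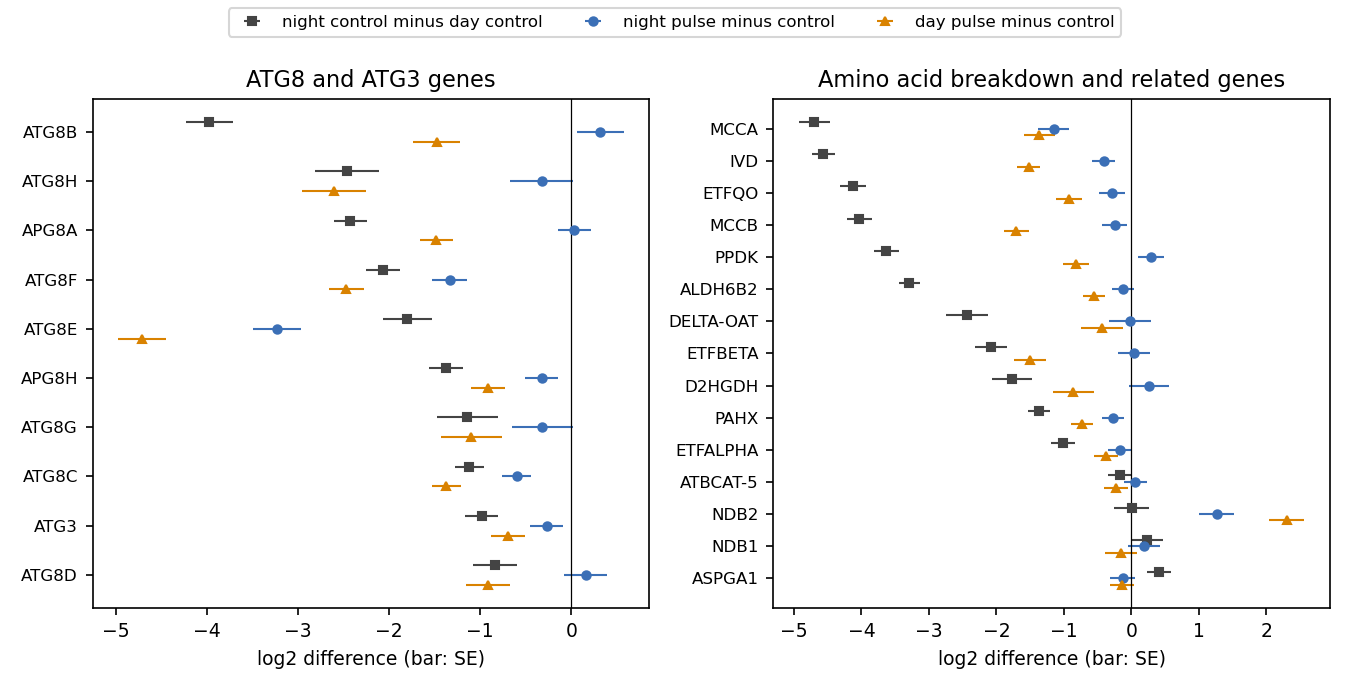
Log2 differences with SE for the 10 autophagy genes and the 15 genes of the branched-chain amino acid breakdown and electron transfer list, PPDK and NDB2 included, with squares for night minus day controls, circles for the night pulse and triangles for the subjective-day pulse. The triangles of all 10 autophagy genes are called falls, against 3 called falls among the circles, whose median is -0.32. The squares of 11 of the 15 genes of the other list are called lower at night.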

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

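The splits of the arrays, the comparison of pulsed with control groups and the relative scaling of the breakdown and ATG8 genes were tests chosen before their results were seen, and the other tests given here were chosen only after the result was seen.

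Of the 89 named genes, 44 differed between the night and the subjective-day pulse by the test of that difference, 19 with negative and 25 with positive values (night minus day effect, log2). AT1G13650 differed by -5.44, AT1G20030 by -5.02, COR15A by -4.74, AT1G51090 by -4.69, AT5G21100 by -4.01 and AT1G70820 by -3.99. AT3G03770 and scpl46 each differed by -3.70, AT5G62140 by -3.59, COR15B by -3.52, AT3G44450 by -3.10 and AT1G06000 by -3.08. HYH differed by -2.33, SWEET17 by -2.27, CaS by -2.20, XTH32 by -2.02, GSTU18 by -1.53, NdhN by -0.91 and SBPASE by -0.72. Positive values were smallest for ATG8C at 0.78, IVD and PPDK at 1.11, ATG8F at 1.13 and AT4G33150 at 1.22. MCCB had 1.46, ATG8E 1.48, APG8A 1.52, ETFBETA 1.54, EXPA16 1.73 and ATG8B 1.80. AT2G20670 had 2.11, GI 2.15, ATG8H 2.28, AT3G19390 2.31, AT1G54740 2.65 and AT1G50040 3.09. The values were 3.26 for AT4G39675, 3.43 for AT4G37220, 3.56 for AT2G32150, 3.60 for ATL8, 3.63 for AT1G69570, 3.64 for AT3G02340, 4.0 for AT2G38820 and 4.87 for AT3G62950. Of the 44, 22 had a group mean under 21.75, so their values depend on dim signals. In 7 of these 22 the dim groups left the difference unmeasured. Both controls were dim for AT1G20030 and AT1G51090, both pulsed groups for AT3G62950 and AT1G50040, and both night groups for AT4G37220, AT3G19390 and AT4G39675. For AT2G20670 and ATL8 the dim night pulse group leaves open a fall at night as large as that in the subjective day. With all signals raised to at least 21.75, 11 of the other 13 were still called in that direction, while GI (0.74, adjusted p = 0.117) and AT1G06000 (-0.72, adjusted p = 0.15) were not. Another 6 of the 89 were called then and not by the reported fit, AT1G20070 (-1.56), AT3G07350 (2.95), AT4G16000 (1.91), AT1G19530 (2.21), SWEET13 (-1.53) and NdhL (-0.72), of which only AT1G20070 and NdhL had no dim group. AT1G20070, AT3G07350, AT4G16000, AT1G19530 and NdhL gained the call under 7, 7, 6, 2 and 5 alternatives in all. Of the 44, 29 were called under every alternative in which they were tested, among them AT1G20030, AT1G51090, AT3G62950, AT4G37220, AT3G19390 and ATL8, whose differences are not established for the reason given, and 15 were not, with SBPASE not called under 17 of 24 alternatives, NdhN 14, AT4G33150 13, ATG8C and EXPA16 12, GI 11 and AT4G39675 9 of 19.

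Of 100 regroupings of the arrays within each time, after the additive effects were taken out, 1 called as many probe sets for the difference between the pulses, the real grouping with 1728. The highest other called 829, which argues against chance for that count but does not exclude it. The real difference stayed in the values, so other groupings had a larger spread, which lowers their counts. For the night pulse, the subjective-day pulse and the controls 1 of 10 splits each, the real ones with 1760, 5833 and 6602, called as many and the highest other called 0. Those 10 splits are too few for a share under 0.05.

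More probe sets were called after the subjective-day pulse than after the night pulse, by a ratio of 3.31, or 1.72 with each pair of groups fitted alone (4502 and 2617 calls), where the larger residual SD of the day groups (0.498 and 0.449, against 0.363 and 0.282) is not pooled with the others and stays open as part of the cause. Array scaling as the whole cause was argued against for the fit of all groups together, since the ratio there was 5.56 without normalization and 3.92 with median centring, with 3.31 the lowest of the 3. Without both arrays with a high GAPDH ratio it was 2.12, and 1.53 to 3.00 with 1 further array left out, so these arrays stay open as part of the cause. The pulsed groups differed in 4761 probe sets, 0.721 times as many as the controls (0.584 to 0.833 with 1 array left out), so controls that lay farther apart also stay open. That the clock sets the size of the response to light is an untested biological explanation that stays open as well.

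The 25 genes of the branched-chain breakdown and electron transfer list and of the autophagy list, among them IVD, MCCB and ATG8B, were lower in the night than in the subjective-day controls by a median of -1.82 log2 relative to all probe sets. A factor per array cancels in this relative shift, so that no normalization and median centring must both give -2.07. Scaling was argued against because the shift not taken relative to other probe sets was -1.80, -1.52 and -2.25 with quantile, no and median scaling. With 1 array left out, always under quantile normalization, the relative shift was -1.95 to -1.77, which does not bear on scaling. A difference in hours of darkness before sampling may account for the lower values at night. The same genes shifted by -0.88 after the subjective-day pulse and by -0.15 after the night pulse. Hours of darkness and clock time cannot be told apart, because each time was sampled once, and the hours of darkness are not given in the sources used here.

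Plastid-encoded genes such as psbF and rpl32 differed between replicates, with a mean log2 of 8.37 on night pulse replicate 3 against 10.4 and 10.28 on the other night pulse arrays. RNA degradation as read by the GAPDH ratio could account for this only if both moved together, and over the 12 arrays r was -0.01 (permutation p = 0.979) and rho -0.06 (permutation p = 0.87), with r = 0.04 without the 2 farthest arrays. The 95% interval of r, -0.58 to 0.57, leaves this open. The 3' to 5' ratio of actin was highest on night pulse replicate 3, at 37.1, against 13.5 to 27.7 on the other arrays. Its ubiquitin ratio was 2.27, within the range of 2.19 to 3.39 over all arrays. Neither ratio was tested against the plastid-encoded genes, so RNA quality on this array stays open. No biological explanation was tested.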

How the results depend on the processing

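Leaving out both arrays with a high GAPDH ratio, raising signals to at least 21.75, and testing lists with median centring or without night pulse replicate 3, were tests chosen only after the data were seen. Without normalization 669 probe sets were called for the night pulse, 3721 for the subjective-day pulse and 439 for the difference, with median centring 2728 for the difference, and with array weights, whose fit stopped before it converged, 3513 for the night pulse and 5308 for the difference. At an adjusted p under 0.01 there were 988 for the night pulse and 711 for the difference, and with at least a 2-fold change 1119 for the night pulse, 3698 for the subjective-day pulse and 4169 for the controls, fewer because the threshold is stricter. With 1 array left out the night pulse ranged from 1105 (without night control replicate 2) to 2295, the subjective-day pulse from 4728 to 6162, the difference from 1147 (without night control replicate 3) to 2650 (without day control replicate 1), the controls from 5531 to 7429 and the share of night calls found again in the subjective day from 76.3% to 86.2% around 81.6%. Other counts stayed within 1.5 times the reported ones, and without both arrays with a high GAPDH ratio they were 2551, 5396, 1982 and 6989, and with signals raised to at least 21.75 1959, 5956, 1994 and 6851. Camera called 0 lists for each of the 4 comparisons with an estimated correlation, where fry called 12 for the subjective-day pulse, 9 for the difference and 12 for the controls. Camera called 3 without normalization for the subjective-day pulse and 3 for the controls, and 8 for the controls without a filter. Of 3557 alternative values of 145 named gene results, 3487 kept their direction and side of the threshold, 51 lost a call, 17 gained one and 2 changed sign. PRK went from 0.47 to -0.16 between controls with median centring, and HEMA2, never called by the reported fit, from -0.22 to 0.03 after the subjective-day pulse without day pulse replicate 3 (-0.57 without replicate 1). Except for the stricter thresholds, the cause was not tested. No named gene had several tested probe sets, so the mean over them gave no value. Signal over background limits the genes with a mean under 21.75 in a group, for which folds are lower bounds, and with raised signals the differences of GI and AT1G06000 and the subjective-day rise of SWEET4 lost a call (adjusted p = 0.117, 0.15 and 0.152). Of 44 named genes with a called difference between pulses, 29 kept the call under every alternative that tested them, some with dim groups that leave the difference unmeasured, a count chosen only after the data were seen.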

Other observations

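The lists described here, and the genes named from lists other than tubulin, cell wall and photorespiration, were chosen only after their values were seen, as was the choice to run those genes under the alternatives, of which there were up to 25 per gene. Several growth genes differed between the controls. Of 7 tubulin genes, 4 were higher in the night controls, 1 was lower and 2 were not called (adjusted p = 0.066, and adjusted p = 0.35 with an estimated correlation), with 5 higher and 0 lower without normalization. TUA6 (AT4G14960) was higher by 2.14 ± 0.30, TUB5 (AT1G20010) by 1.91 ± 0.28, TUB9 (AT4G20890) by 1.85 ± 0.20 and TUB7 (AT2G29550) by 1.32 ± 0.23, all of them subunits of microtubules. Of 15 expansin and xyloglucan endotransglucosylase genes, which loosen and remodel the cell wall, with EXO, an EXORDIUM protein of neither family, counted among them, 9 were higher at night, 2 lower and 4 not called (adjusted p = 0.126, and adjusted p = 0.51 with an estimated correlation), and 3 were lower with median centring. XTH32 (AT2G36870) was higher by 2.25 ± 0.17 and EXO (AT4G08950) by 1.60 ± 0.36, while EXPA16 (AT3G55500) was at -2.09 ± 0.38 and EXLA1 (AT3G45970) at -1.67 ± 0.37. Of 4 photorespiration and Calvin cycle genes, SBPASE, RCA (AT2G39730) and PRK (AT1G32060) were higher at night and HPR (AT1G68010) was lower, also when adjusted over the list alone (adjusted p = 0.292, and adjusted p = 0.51 with an estimated correlation), but with median centring 1 was higher and 1 lower. RCA was higher by 1.02 ± 0.19 and lost its call with median centring (adjusted p = 0.232), as did PRK, at 0.47 ± 0.12 (adjusted p = 0.466, with the sign changed), which also lost it without a filter (0.0501).

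Of 2 auxin genes and 1 shade gene tested from the lists fixed in advance, 1 of each list fell after the subjective-day pulse. WES1 (AT4G27260), which joins auxin to amino acids, fell from 1447 ± 314 to 90.3 ± 37.8, a change of -4.02 ± 0.35, and differed from the night effect by 2.88 ± 0.49. HAT2 (AT5G47370), a homeodomain factor of shade and auxin response, fell by 1.99 ± 0.27. The morning clock gene AT5G52660 rose by 1.33 ± 0.32 in the subjective day and changed by 0.72 ± 0.32 at night without a call, though 3 of its alternatives called it. Of 2 starch breakdown genes, PWD (AT5G26570) rose by 0.85 ± 0.21 and DPE1 (AT5G64860) fell by 1.04 ± 0.22 in the subjective day. Both lost the call without normalization (adjusted p = 0.118 and 0.0562), and PWD also with median centring (0.0602). The 4 reference genes listed in advance were not all stable, since AT4G34270 and PEX4 (AT5G25760) fell by 0.70 and 0.61 log2 after the day pulse, each call lost under 4 alternatives. After that pulse 0 were lower without normalization and 3 with median centring. In the night controls 1 was higher and 3 lower, against 0 and 0 without normalization and 0 and 3 with median centring. None of 10 mitochondrion-encoded genes was called by limma in any comparison, nor had any an unadjusted p under 0.05, although 5 of them, ccb382, ccb452, nad4, nad1 and cox1, were called in 1 or more comparisons under 1 to 3 alternatives, array weights among them for each. Without normalization 1 of the 9 tested was called higher in the night controls. Of 26 plastid-encoded photosystem genes, 7 rose after the subjective-day pulse (adjusted p = 0.064, and adjusted p = 0.75 with an estimated correlation), against 1 under each other scaling, and the list had an adjusted p = 0.0484 without night pulse replicate 3.

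Of 3 light-harvesting antenna genes, 1 rose at night and 2 rose in the subjective day (1 under each other scaling). LHCB4.3 (AT2G40100) rose after both pulses, by 1.02 ± 0.31 and 1.06 ± 0.31, LHCB4.2 (AT3G08940) rose by 0.91 ± 0.33 in the subjective day, a call lost under 13 alternatives, and LHCB4.3, whose night call was lost under 10 and day call under 1, was higher by 2.62 ± 0.31 in the night controls, where the list had a median of -0.21 and a mean above 0. Of 4 oxidative and high-light stress genes, SAPX (AT4G08390), a chloroplast ascorbate peroxidase, rose by 1.11 ± 0.22 in the subjective day, none was called for the night pulse and 3 were higher in the night controls (2 with median centring). Of 12 calmodulin-like, U-box and other early stress genes, PUB19 (AT1G60190) rose by 2.99 ± 0.61 at night, and 3 rose and 2 fell (1 without normalization) in the subjective day, among them WRKY22 (AT4G01250), lower by 2.91 ± 0.32. The carotenoid gene LYC (AT3G10230) rose by 0.39 ± 0.14 in the subjective day, but lost the call under 9 alternatives, among them no normalization (0.32, adjusted p = 0.471) and median centring (-0.02, adjusted p = 0.944). SIR (AT5G04590), of sulfur assimilation, and LIL3:2 (AT5G47110), a light-harvesting-like protein, were higher in the night controls by 1.43 ± 0.19 and 1.12 ± 0.15, and WRKY53 (AT4G23810) was at -1.66 ± 0.34. The root marker PYK10 (AT3G09260) was higher by 0.75 ± 0.26 in the night controls, a call lost under 6 alternatives, among them median centring (0.25, adjusted p = 0.436). The guard cell marker FMA (AT3G24140) was not called in any comparison, though 3 alternatives called it between the controls. Camera called none of these lists with at least 3 tested genes. No gene was tested from the lists of photoreceptors, clock outputs, heat shock, phloem, epidermis and flower genes.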
